A study of Mus musculus with 11 samples.

How the data were processed

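Kidneys of mice kept on the 0.2% adenine diet for 14 days after tamoxifen (0.5 mg/kg) were digested with Liberase, trypsin and DNase, passed through a 40 µm strainer, freed of red cells and run on a 10x Chromium 3' kit, per the labels. There were 3 cre-negative, 4 Col5a1 knockout and 4 knockout libraries with cilengitide (20 mg/kg every other day). The files hold raw UMI counts (each count a distinct transcript molecule) per gene and barcode, deposited as 1 filtered matrix per library. The submitters' notes name Cell Ranger 3.0.2, Seurat 3.0.2 and the build GRCm39. The gene annotation release, the aligner settings and the cell calling are not given in the sources used here. The annotation at hand was of an earlier build, so no gene coordinates are given. The files list the same 33696 genes, and 26 symbols on more than 1 line were kept apart.

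The libraries held 87468 barcodes in all, 1498 to 11326 per library, and between 29.8 and 85.6 UMIs each in units of 1e6. Mean totals in that unit were 76.5 ± 4.15 (SD, n = 4) in the knockout, 80.5 ± 5.19 (n = 4) with cilengitide and 50.0 ± 20.9 (n = 3) in the cre-negative group. The median UMIs per barcode averaged 4273, 5030 and 8874, and the median mitochondrial share 3.26%, 4.46% and 12.9%. Barcodes with under 200 genes (2063) or with 50% or more mitochondrial UMIs (7281) were left out. Doublets were scored from simulated pairs (2 per cell, 50 neighbours), and in each library the highest scores were removed at 0.8% per 1000 barcodes (6186 barcodes), which left 73946 cells, 1382 to 9693 per library. No pair of libraries shared its counts by a duplicate check (chi-square per degree of freedom 15.8 to 159 in 15 pairs within groups, 35.5 to 544 in 40 between). All libraries were male by X- and Y-linked transcripts, so no sex covariate was run.

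Cells were clustered on 2000 variable genes without 37 matrix genes, 30 principal components and 20 neighbours with the Leiden algorithm at resolution 1, which gave 41 clusters. A cluster took the name of a marker list when at least 3 of its markers were among the 100 genes of highest fold over the other clusters (at least 50 CPM, prior 10 CPM) and at least 3 were seen in 10% of its cells, unless another list led among the 10 genes of highest fold. The lists were written before the data were examined, and names end in -like. 4 clusters with 5321 cells (7.20%) stayed unnamed and were not tested for genes; they held 2.81%, 1.33%, 1.18% and 0.426% of knockout cells, 6.08%, 2.50%, 0.913% and 0.447% of cre-negative cells, and 4.56%, 1.20%, 1.16% and 0.833% with cilengitide.

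UMIs were summed per gene, class and library (CPM, UMIs per 1e6; TMM-normalized per fit for genes past the test, dividing by total UMIs alone for Col5a1, integrins and fibrillar collagens in fibroblast-like cells and MHC class II genes). Libraries with at least 10 cells of a class entered, with at least 2 per group. Only 1 cre-negative library had 10 fibroblast-like cells, so for knockout against cre-negative the minimum was lowered to 5, a choice made after the cell numbers were seen. Counts were tested with the edgeR quasi-likelihood F-test (TMM, filterByExpr, all 3 groups in 1 fit) and adjusted by Benjamini-Hochberg over the genes of a class and contrast at 0.05. Standard errors are the log2 fold change over the square root of F. Class shares were compared by exact permutation of the libraries, counting differences of either sign (35 labellings for 3 against 4, 70 for 4 against 4; smallest p = 0.0286) and adjusted over 14 classes.

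21 gene lists were written before the data were examined: collagen and matrix, contractile myofibroblast, TGF-beta response, integrin and focal adhesion, inflammatory cytokine and NF-kB, interferon response, MHC class II, tubule injury, proximal tubule transport, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, cell cycle, p53 and senescence, immediate early and dissociation, heat shock, glycolysis and hypoxia, scar-associated macrophage, endothelial activation and angiogenesis, oxidative stress and metallothionein, and circadian and glucocorticoid. They were tested with limma camera (preset correlation 0.01), again with an estimated correlation, and with fry, which asks whether the genes of a set move one way on balance. A list's signs of median, mean and test were the same in every list that passed. Of their genes 12 are in more than 1 list.

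Genes were named by a rule fixed before the data were examined: Col5a1, Itgav, Itgb3 and Itgb5 in fibroblast-like cells; per contrast the 5 largest rises and falls in fibroblast-like and proximal tubule-like cells and the 2 largest elsewhere, among genes past the test with at least 20 CPM in the higher group and no overlap between the groups' libraries; where fewer than 3 passed, the 3 of smallest p; and up to 4 members of a list. 3 genes chosen by the rule are not reported here. Sex-linked, immunoglobulin, haemoglobin and predicted genes were not eligible. Chance gives no overlap in 5.71% of genes for 3 against 4 and 2.86% for 4 against 4. A gene was called open to free RNA when its CPM in the class was under 0.2 of that of the whole library in the higher group. That rule, the tests in 7 further classes and the shares outside leukocyte classes were chosen after the data were seen. For genes with few UMIs the ratio of the groups is given with its exact Poisson interval, which covers counting error only.

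The gene test was tried on simulated negative binomial counts with each class's mean, spread and depth, 1 mean in all libraries and 200 genes changed 1.5- to 4-fold in 1 group. It recovered 74.5% and 79% of them in proximal tubule-like cells in the 2 contrasts (15 of 164 and 14 of 172 calls were false), 48.5% and 73% in macrophage-like cells, and 19% and 23% in fibroblast-like cells. With no change it made 0 calls in classes tried, and 0 or 1 of 100 random lists per class had camera p under 0.05. Co-expressed lists were not tried. Alternatives were DESeq2, RLE size factors, no low-count filter, a replicate block, only the compared groups in the fit, doublets kept, a mitochondrial limit of 20%, Leiden resolution 2 (58 clusters), thinning to equal UMIs, and leaving out each library. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.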

Results

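Kidney cells of 11 mouse libraries were profiled by droplet-based 3' single-cell RNA sequencing after 14 days on a diet with 0.2% adenine, which injures the tubules and scars the kidney. 3 libraries came from cre-negative mice, 4 from mice in which Col5a1, the gene for the alpha 1 chain of type V collagen, was deleted with a Col1a2-driven, tamoxifen-induced Cre (the knockout), and 4 from knockout mice given cilengitide, an inhibitor of αv integrins. All 3 groups ate the adenine diet, so no comparison measured the effect of the diet, and no cre-negative mice were given cilengitide. After filtering, 73946 cells were retained and 14 cell classes were named from marker genes, from 192 mast cell or basophil-like cells to 19298 T or NK cell-like cells. The p-values measure only the spread between libraries, and the labels do not say whether each library was a separate animal.

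The kidneys of the knockout group held larger shares of leukocytes and smaller shares of tubule, endothelial and fibroblast-like cells than those of the cre-negative group. T or NK cell-like cells made up 29.5% ± 1.46 (SD, n = 4) of retained cells in the knockout and 16.4% ± 7.24 (SD, n = 3) in the cre-negative group, and neutrophil-like cells 20.9% ± 0.538 and 6.84% ± 4.98. Macrophage-like cells rose from 2.33% ± 0.705 to 9.54% ± 1.44, dendritic cell-like cells from 0.458% ± 0.310 to 3.29% ± 0.652, and B or plasma cell-like cells from 1.19% ± 0.834 to 3.69% ± 0.610. Proximal tubule-like cells, the reabsorbing epithelium of the cortex, fell from 26.8% ± 4.07 to 13.2% ± 1.69, thick ascending limb-like cells from 19.9% ± 9.12 to 4.78% ± 0.599, and distal tubule-like cells from 6.19% ± 4.03 to 2.24% ± 0.223. Endothelial-like cells fell from 4.45% ± 1.35 to 1.95% ± 0.680, and fibroblast-like cells from 0.500% ± 0.209 to 0.227% ± 0.0144. For each of these 10 classes all 4 knockout libraries lay on one side of all 3 cre-negative libraries, which gave p = 0.0286 by an exact permutation test, the smallest p that 35 labellings allow, and a Benjamini-Hochberg adjusted p of 0.04 over 14 classes.

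Injured tubule-like cells made up 3.19% ± 0.256 (n = 4) and 3.19% ± 0.513 (n = 3) of cells, with p = 1 by the exact permutation test. Pericyte or smooth muscle-like cells made up 0.820% ± 0.0495 and 0.894% ± 0.491, with an adjusted p of 0.677 by the exact permutation test. Mast cell or basophil-like cells (0.297% and 0.129%; adjusted p = 0.109) and cycling cells (0.560% and 0.806%; adjusted p = 0.233) did not pass the exact permutation test either. Leukocyte classes together made up 67.3% ± 2.74 of the knockout and 27.3% ± 14.1 of the cre-negative cells (exact permutation p = 0.0286, adjusted p = 0.0476). Shares sum to 100%, so a larger share of leukocytes lowers every other share. Injured tubule-like cells kept the same share of all cells, so they made up more of the cells outside the leukocyte classes in the knockout. Among cells outside the leukocyte classes, the share of proximal tubule-like cells was 3.29 percentage points higher in the knockout (exact permutation p = 0.457), the opposite sign of its share of all cells. On that base the fibroblast-like difference was -0.0402 points and the endothelial-like difference -0.528 points, both with an exact permutation p of 0.886. Shares also depend on the yield of each class through enzymatic dissociation, a 40 µm strainer and red cell lysis. The cre-negative group had 1498 to 8683 barcodes per library and the other groups 7301 to 11326.

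Cilengitide in knockout mice changed no class share past the adjusted threshold. T or NK cell-like cells made up 25.5% ± 1.52 (SD, n = 4) with cilengitide against 29.5% ± 1.46 (n = 4) without, and pericyte or smooth muscle-like cells 1.21% ± 0.0800 against 0.820% ± 0.0495. In both classes the 4 libraries of one group lay on one side of the other 4 (exact permutation p = 0.0286, adjusted p = 0.2). Endothelial-like cells made up 2.84% with and 1.95% without the drug (exact permutation, adjusted p = 0.24), injured tubule-like cells 4.91% ± 1.72 and 3.19% ± 0.256 (adjusted p = 0.286), and fibroblast-like cells 0.496% ± 0.300 and 0.227% ± 0.0144 (adjusted p = 0.286). Proximal tubule-like cells made up 13.1% ± 3.37 and 13.2% ± 1.69, and macrophage-like cells 10.7% ± 3.12 and 9.54% ± 1.44 (exact permutation, adjusted p = 1 and 0.767). An edgeR quasi-likelihood test on the cell numbers called the same 10 classes between knockout and cre-negative libraries, with an adjusted p of 0.0491 for fibroblast-like cells, and also mast cell or basophil-like cells (adjusted p = 0.0152). It called no class for cilengitide, where the smallest adjusted p was 0.222.

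**Figure D1:**
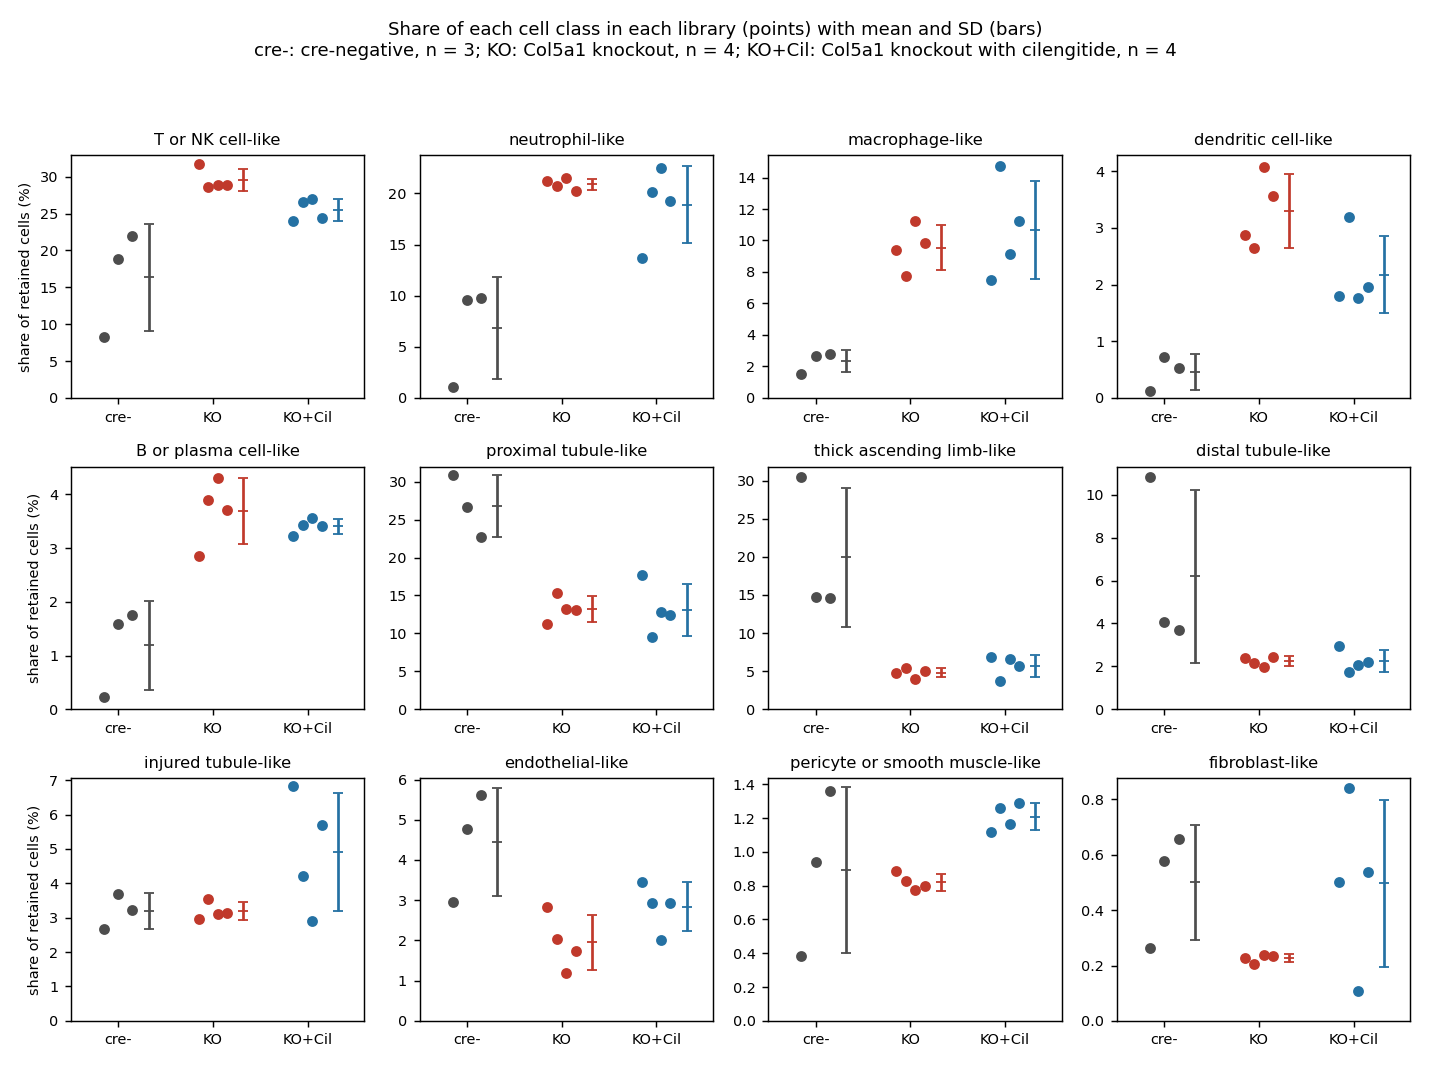
Percentage of the retained cells of each library in 12 cell classes (points) with the group mean and SD (bars), for cre-negative (n = 3), Col5a1 knockout (n = 4) and knockout with cilengitide (n = 4). Every knockout library lies above every cre-negative library in the 5 leukocyte classes drawn and below it in the tubule, endothelial and fibroblast-like classes, except injured tubule-like cells.

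In fibroblast-like cells, the class in which the Cre driver is active, the transcript of the deleted gene Col5a1 (ENSMUSG00000026837) reached 56.5 ± 31.0 CPM (SD, n = 4) in the knockout, 94.9 ± 33.9 (n = 4) with cilengitide and 213 ± 149 (n = 3) in cre-negative libraries. These levels rest on 287 fibroblast-like cells in all, 8 to 68 per library, and on 4 to 85 Col5a1 UMIs per library. With libraries of at least 5 cells, the log2 fold change of the knockout was -1.96 ± 0.51 (SE), with an adjusted p of 0.0974 by the edgeR quasi-likelihood test. The tags read the 3' end of the transcript and need not cover the deleted exons, so this level checks nothing about the deletion. The αv integrin subunit gene Itgav (ENSMUSG00000027087), whose product cilengitide binds, stood at 521 ± 274 CPM in the knockout, 402 ± 148 with cilengitide and 216 ± 114 in cre-negative libraries. Its log2 fold change in the knockout was 1.18 ± 0.46 (adjusted p = 0.239; 0.72 without knockout 2), and that of its partner Itgb5 (ENSMUSG00000022817) -0.60 ± 0.34 (adjusted p = 0.443; -0.37 without knockout 3). Itgb3 (ENSMUSG00000020689), the other partner blocked by the drug, reached 1.23, 12.9 and 2.74 CPM in the 3 groups and was too low to test. Other fibrillar collagen genes stood at 939 ± 726 and 3897 ± 2285 (Col1a1 (ENSMUSG00000001506)), 885 ± 696 and 3290 ± 678 (Col3a1 (ENSMUSG00000026043)), and 256 ± 189 and 453 ± 22.2 (Col5a2 (ENSMUSG00000026042)) CPM in the knockout and cre-negative groups.

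**Figure D2:**
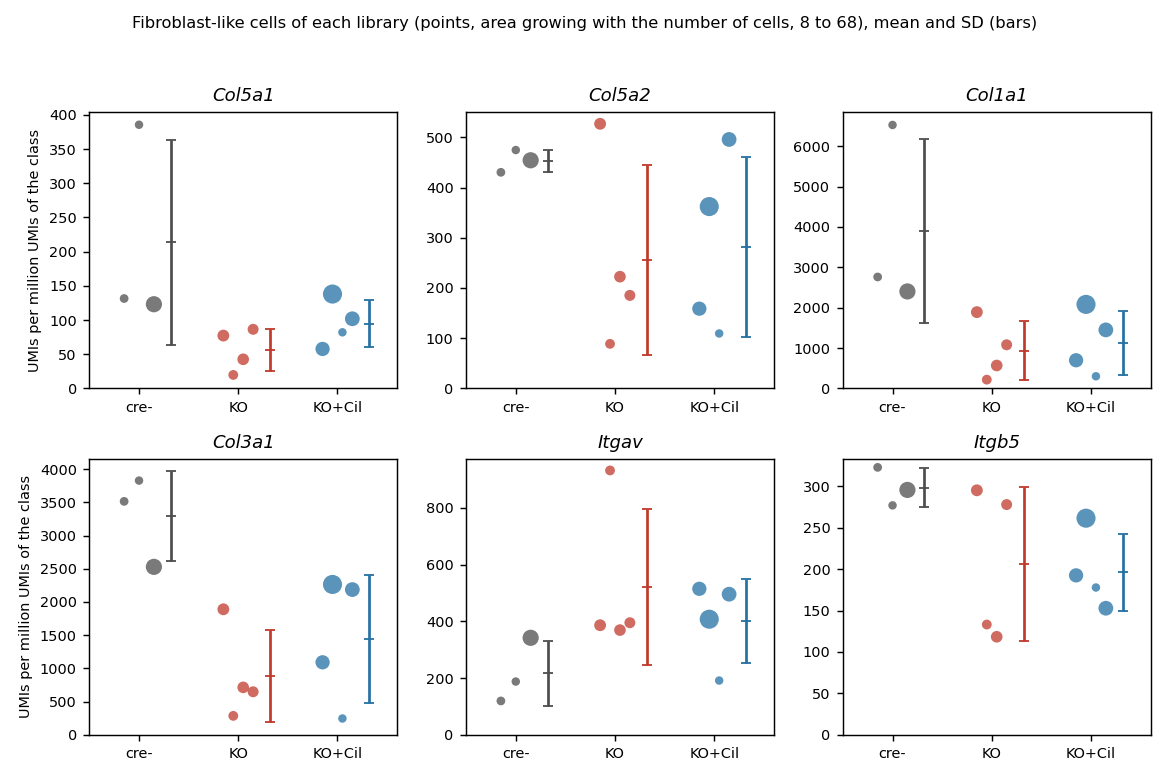
CPM of the fibroblast-like cells of each library for Col5a1, Col5a2, Col1a1, Col3a1, Itgav and Itgb5, with points whose area grows with the number of cells (8 to 68) and bars for the mean and SD of cre-negative (n = 3), knockout (n = 4) and cilengitide (n = 4) libraries. Col5a1 has a mean of 56.5 in the knockout, 94.9 with cilengitide and 213 in the cre-negative group.

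Several genes for matrix proteins were lower in fibroblast-like cells of the knockout than of the cre-negative group (n = 4 and 3 libraries with at least 5 cells, log2 fold change ± SE). Rbp4 (ENSMUSG00000024990, retinol carrier) fell by 6.96 ± 1.09 (adjusted p = 0.0171) and Smoc2 (ENSMUSG00000023886, secreted matrix protein) fell by 4.82 ± 0.78 (adjusted p = 0.0175). Fbln1 (ENSMUSG00000006369, fibulin 1) fell by 4.09 ± 0.61 (adjusted p = 0.0171) and Mfap4 (ENSMUSG00000042436, microfibril protein) fell by 3.94 ± 0.67 (adjusted p = 0.0245). Cygb (ENSMUSG00000020810, cytoglobin) fell by 3.39 ± 0.46 (adjusted p = 0.00869). Smoc2 stood at 15.4 ± 17.4 CPM in the knockout and 494 ± 159 in cre-negative libraries, and Cygb at 66.2 ± 38.3 and 695 ± 293. The largest rises were in Pkp2 (ENSMUSG00000041957, desmosomal plakophilin) (4.35 ± 0.79; adjusted p = 0.0351), Gprc5a (ENSMUSG00000046733, orphan receptor of epithelia) (3.62 ± 0.72; adjusted p = 0.0403), Cryab (ENSMUSG00000032060, small heat shock protein) (2.31 ± 0.45; adjusted p = 0.0403), Hmgb3 (ENSMUSG00000015217, chromatin protein) (2.05 ± 0.41; adjusted p = 0.0403) and Slc6a6 (ENSMUSG00000030096, taurine transporter) (2.05 ± 0.42; adjusted p = 0.0452). Cryab stood at 1178 ± 463 and 237 ± 48.5 CPM. The groups' libraries did not overlap in these 10 genes. Admixture of epithelial cells, which could shift both matrix genes and Gprc5a, was not tested. With 1 library left out only Fbln1 and Cygb held their calls in every run. The calls of Rbp4 and Smoc2 were lost in 3 of 7 runs, Mfap4 in 4, Cryab and Slc6a6 in 5, Gprc5a and Hmgb3 in 6, and Pkp2 in 3 of 4 (highest adjusted p 0.106 to 0.177). Without cre-negative 3, Pkp2 had 7.12 and Gprc5a 7.26. In all, 6 genes rose and 24 fell among 4807 tested. Rbp4 rested on 1 UMI in the knockout against 100 (ratio of cre-negative to knockout 131, 95% exact counting interval 22.9 to 5208), and Pkp2 on 62 against 2 in cre-negative libraries (ratio of knockout to cre-negative 23.7, interval 6.30 to 200.4).

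Among gene lists written in advance, the collagen and matrix list was lower in knockout fibroblast-like cells. Its 35 tested members had a median log2 fold change of -1.04, 5 of them fell over all genes, 14 adjusted over the list alone, and camera gave an adjusted p of 2.98e-13. It no longer passed (adjusted p = 0.18 with an estimated correlation). Sparc (ENSMUSG00000018593, osteonectin) fell by 1.88 ± 0.35 and Col6a1 (ENSMUSG00000001119, type VI collagen) fell by 2.38 ± 0.48, and Fbln1 and Mfap4 were also among its members. The interferon response list was lower, with a median of -1.22 over 9 members and 1 gene past the test over all genes and 4 adjusted over the list alone (adjusted p = 3.22e-04, but adjusted p = 0.29 with an estimated correlation). Ifi27l2a (ENSMUSG00000079017, interferon-induced) fell by 2.64 ± 0.49, and Bst2 (ENSMUSG00000046718, tetherin) had -1.57 ± 0.38 (adjusted p = 0.089). The contractile myofibroblast list had a median of -0.81 over 14 members, 0 past the test over all genes and 2 adjusted over the list alone (adjusted p = 0.00971, but adjusted p = 0.343 with an estimated correlation). The MHC class II list had a median of 2.66 over 4 members, 0 past the test over all genes and 4 adjusted over the list alone (adjusted p = 0.00131, but adjusted p = 0.343 with an estimated correlation). All 4 members, H2-Ab1 (ENSMUSG00000073421), Cd74 (ENSMUSG00000024610), H2-Aa (ENSMUSG00000036594) and H2-Eb1 (ENSMUSG00000060586), were below 0.2 of the CPM of the whole library and so open to free RNA. The tubule injury list had a median of 1.01 over 21 members, 0 past the test over all genes and 2 adjusted over the list alone (adjusted p = 0.0137, but adjusted p = 0.441 with an estimated correlation). The integrin and focal adhesion list had a median of 0.08 over 14 members and did not pass (adjusted p = 0.923). The test recovered 19% of 200 genes changed in simulated data, so many changes of this class were not detectable.

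Proximal tubule-like cells of the knockout differed from those of the cre-negative group in 1903 genes (n = 4 and 3 libraries). Slco1a1 (ENSMUSG00000041698) fell by 3.15 ± 0.34 (log2 fold change ± SE, adjusted p = 3.56e-05), from 166 ± 15.7 to 18.7 ± 4.40 CPM (SD). Slc7a13 (ENSMUSG00000041052, amino acid transporter of the straight segment) fell by 2.66 ± 0.26 (adjusted p = 2.29e-05), from 257 ± 39.8 to 40.8 ± 18.4 CPM. Ldc1 (ENSMUSG00000023120) fell by 2.89 ± 0.22 (adjusted p = 2.37e-06) and Cyp4a12a (ENSMUSG00000066071) by 2.68 ± 0.17 (adjusted p = 5.86e-07). Cyp2d12 (ENSMUSG00000096852) fell by 2.26 ± 0.48 (adjusted p = 0.00552). Shifts between clusters of the class (only 1 fell, from 27.9% to 18.3%) were not separated from expression. Fabp1 (ENSMUSG00000054422) rose by 3.32 ± 0.52 (adjusted p = 6.57e-04), from 3.05 ± 0.502 to 31.0 ± 25.6 CPM (2.56 without knockout 1). Il1b (ENSMUSG00000027398, interleukin 1 beta of myeloid cells) rose by 3.06 ± 0.43 (adjusted p = 2.68e-04), S100a9 (ENSMUSG00000056071, neutrophil calprotectin subunit) by 2.73 ± 0.47 (adjusted p = 0.00132) and Srgn (ENSMUSG00000020077, leukocyte proteoglycan) by 2.28 ± 0.37 (adjusted p = 8.07e-04), and all 3 were open to free RNA. The groups' libraries did not overlap in these 9 genes. In all, 1006 genes rose and 897 fell among 13472 tested (727 and 882 not open to free RNA).

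Markers of injury rose in these cells. Tubule injury genes had a median log2 fold change of 1.02 over 28 members, of which 20 rose over all genes and 21 adjusted over the list alone (camera, adjusted p = 2.6e-19, and adjusted p = 0.0456 with an estimated correlation). Wfdc2 (ENSMUSG00000017723) rose by 1.41 ± 0.14, Spp1 (ENSMUSG00000029304, osteopontin) by 1.14 ± 0.15 and Lgals3 (ENSMUSG00000050335, galectin 3) by 1.33 ± 0.16, the last open to free RNA. The proximal tubule transport list had a median of -0.21 over 29 members, with 10 lower and 1 higher on either adjustment (adjusted p = 2.1e-07, and adjusted p = 0.0287 with an estimated correlation). Slc22a30 (ENSMUSG00000052562) fell by 1.94 ± 0.17 and Slc5a8 (ENSMUSG00000020062, monocarboxylate transporter) by 1.27 ± 0.11. The scar-associated macrophage list had a median of 0.61 over 16 members, with 11 higher and 1 lower on either adjustment (adjusted p = 1.54e-06, and adjusted p = 0.0379 with an estimated correlation). Free macrophage RNA as its source was not tested. The MHC class II list had a median of 1.78, with 8 of 9 members higher on either adjustment (adjusted p = 6.94e-16, but adjusted p = 0.0583 with an estimated correlation). Cd74 rose by 1.78 ± 0.22, from 77.8 to 271 CPM, H2-Eb1 by 1.96 ± 0.25 and H2-Aa by 2.03 ± 0.26, all open to free RNA.

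Further lists passed with the preset correlation and not with an estimated one. The inflammatory cytokine and NF-kB list had a median of 0.45, with 8 genes higher and 1 lower over all genes and 13 and 1 adjusted over the list alone (adjusted p = 6.25e-05, but adjusted p = 0.334 with an estimated correlation). The collagen and matrix list had a median of 0.49 over 9 members, 5 higher on either adjustment (adjusted p = 4.77e-04, but adjusted p = 0.0583 with an estimated correlation). The oxidative stress and metallothionein list had a median of 0.30, with 8 higher over all genes and 9 adjusted over the list alone (adjusted p = 5.71e-04, but adjusted p = 0.288 with an estimated correlation). The interferon response list had a median of 0.44, with 7 higher over all genes and 9 adjusted over the list alone (adjusted p = 0.00205, but adjusted p = 0.334 with an estimated correlation). Its 4 members of smallest p, Rtp4 (ENSMUSG00000033355), Bst2, Psmb8 (ENSMUSG00000024338) and Tap1 (ENSMUSG00000037321), were open to free RNA. The fatty acid oxidation list had a median of 0.24, with 12 higher and 3 lower over all genes and 13 and 3 adjusted over the list alone (adjusted p = 0.00334, but adjusted p = 0.424 with an estimated correlation). Endothelial activation and angiogenesis (median 0.72; adjusted p = 0.00277, but adjusted p = 0.323 with an estimated correlation) and contractile myofibroblast genes (median 0.30; adjusted p = 0.0212, but adjusted p = 0.334 with an estimated correlation) were higher. Circadian and glucocorticoid genes (median -0.32; adjusted p = 0.0236, but adjusted p = 0.418 with an estimated correlation) and heat shock genes (median -0.20; adjusted p = 0.0308, but adjusted p = 0.411 with an estimated correlation) were lower.

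In injured tubule-like cells of the knockout a pair of organic anion transporter genes fell (n = 4 and 3). Slc22a30 fell by 2.16 ± 0.22 (log2 fold change ± SE; adjusted p = 4.40e-04), from 25.4 ± 5.56 to 5.63 ± 1.55 CPM (SD), and its relative Slc22a28 (ENSMUSG00000063590) by 2.33 ± 0.33 (adjusted p = 0.00570). Cyp4a10 (ENSMUSG00000066072), a target of PPAR-alpha, rose by 2.39 ± 0.44 (adjusted p = 0.0256). Adm (ENSMUSG00000030790, adrenomedullin, a hypoxia-induced vasodilator) rose by 1.06 ± 0.18 (adjusted p = 0.0198), from 36.7 ± 13.6 to 81.5 ± 11.4 CPM. With 1 library left out the calls of Cyp4a10 and Adm were lost in 3 and 1 of 7 runs. In all, 48 genes rose and 77 fell among 12801 tested. The tubule injury list had a median of 0.64, with 4 of 30 members higher over all genes and 10 adjusted over the list alone (camera, adjusted p = 6.32e-15, but adjusted p = 0.153 with an estimated correlation). Sox9 (ENSMUSG00000000567, repair transcription factor) rose by 1.05 ± 0.17 and C3 (ENSMUSG00000024164, complement) by 0.77 ± 0.14. The proximal tubule transport list had a median of -0.54, with 6 of 28 members lower over all genes and 14 adjusted over the list alone (adjusted p = 9.98e-13, but adjusted p = 0.153 with an estimated correlation). The mitochondrially encoded list had a median of -0.59, with 1 of 13 members lower over all genes and 10 adjusted over the list alone (adjusted p = 3.05e-08, but adjusted p = 0.291 with an estimated correlation). Dbp (ENSMUSG00000059824, clock output factor) fell by 1.24 ± 0.19 within a circadian and glucocorticoid list of median -0.22 (4 lower on either adjustment, 1 higher over the list alone; adjusted p = 0.0357, but adjusted p = 0.291 with an estimated correlation). 8 further lists passed with the preset correlation at medians between -0.15 for nuclear-encoded oxidative phosphorylation (adjusted p = 0.0252, but adjusted p = 0.622 with an estimated correlation) and 0.42 for MHC class II (adjusted p = 8.66e-05, but adjusted p = 0.291 with an estimated correlation). Of the 12 lists 0 held with an estimated correlation.

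Endothelial-like cells of the knockout differed from those of the cre-negative group in 104 genes (n = 4 and 3). Fabp5 (ENSMUSG00000027533, fatty acid-binding protein) fell by 1.76 ± 0.24 (log2 fold change ± SE; adjusted p = 0.00233), from 393 ± 208 to 116 ± 18.2 CPM (SD). Tbxa2r (ENSMUSG00000034881, thromboxane receptor) fell by 1.55 ± 0.34 (adjusted p = 0.0326). Halr1 (ENSMUSG00000085412, noncoding RNA of the Hoxa locus) rose by 1.68 ± 0.34 (adjusted p = 0.0239). Nipal2 (ENSMUSG00000038879, magnesium transporter family) rose by 1.64 ± 0.35 (adjusted p = 0.0298). With 1 library left out Fabp5 held its call, and the other 3 each lost it in 4 of 7 runs (highest adjusted p 0.0940 to 0.133). In all, 41 genes rose and 63 fell. Interferon response genes had a median of -0.35, with 6 of 23 members lower over all genes and, adjusted over the list alone, 10 lower and 1 higher (camera, adjusted p = 5.46e-11, but adjusted p = 0.22 with an estimated correlation). Ifi44 (ENSMUSG00000028037) fell by 0.77 ± 0.13 and Bst2 by 0.84 ± 0.15. The endothelial activation and angiogenesis list had a median of -0.18, with 3 lower over all genes and, adjusted over the list alone, 7 lower and 2 higher (adjusted p = 0.0176, but adjusted p = 0.257 with an estimated correlation). The inflammatory cytokine and NF-kB list had a median of 0.39, with 1 of 17 members higher over all genes and 7 adjusted over the list alone (adjusted p = 3.6e-07, but adjusted p = 0.167 with an estimated correlation). MHC class II (median -0.53; adjusted p = 0.00468, but adjusted p = 0.506 with an estimated correlation) and glycolysis and hypoxia genes (median -0.18; adjusted p = 0.0135, but adjusted p = 0.414 with an estimated correlation) were lower. They had 0 members past the test over all genes and 3 and 2 adjusted over the list alone.

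Macrophage-like cells had higher oxidative stress and lower interferon response genes in the knockout than in the cre-negative group (n = 4 and 3). Srxn1 (ENSMUSG00000032802, sulfiredoxin) rose by 1.53 ± 0.19 (log2 fold change ± SE; adjusted p = 0.00363), from 24.6 ± 9.75 to 75.1 ± 9.42 CPM (SD). Bcar3 (ENSMUSG00000028121, integrin signalling adaptor) had 1.47 ± 0.31 (adjusted p = 0.0456; 1.02 without cre-negative 3). Mgp (ENSMUSG00000030218, matrix Gla protein) fell by 2.01 ± 0.32 (adjusted p = 0.0192) and Akr1c21 (ENSMUSG00000021207, tubule steroid dehydrogenase) by 1.61 ± 0.28 (adjusted p = 0.0333), the last open to free RNA. Without 1 library the calls of Bcar3, Akr1c21 and Mgp were lost in 6, 4 and 1 of 7 runs. In all, 53 genes rose and 31 fell among 12627 tested. A fit of these groups alone called 0, on 37 to 200 cells per cre-negative library. The oxidative stress and metallothionein list had a median of 0.30, with 4 of 20 members higher over all genes and 8 adjusted over the list alone (camera, adjusted p = 2.34e-07, and adjusted p = 0.0261 with an estimated correlation). Fth1 (ENSMUSG00000024661, ferritin heavy chain) rose by 0.58 ± 0.11 and Slc7a11 (ENSMUSG00000027737, cystine transporter) by 1.30 ± 0.27. The interferon response list had a median of -0.59, with 5 of 24 members lower over all genes and 16 adjusted over the list alone (adjusted p = 3.58e-22, and adjusted p = 0.0424 with an estimated correlation). Oasl2 (ENSMUSG00000029561) fell by 0.84 ± 0.14, Ifit1 (ENSMUSG00000034459) by 1.55 ± 0.30 and Ifit3 (ENSMUSG00000074896) by 1.23 ± 0.25. The cell cycle list had a median of -0.91, with 0 of 25 members past the test over all genes and, adjusted over the list alone, 16 lower and 1 higher (adjusted p = 3.34e-15, but adjusted p = 0.195 with an estimated correlation). Ccnb2 (ENSMUSG00000032218) had -0.89 ± 0.25 (adjusted p = 0.1). The scar-associated macrophage list had a median of 0.41, with 0 of 22 members past the test over all genes and, adjusted over the list alone, 5 higher and 1 lower (adjusted p = 5.3e-05, but adjusted p = 0.469 with an estimated correlation). Arg1 (ENSMUSG00000019987) had 1.89 ± 0.43 (adjusted p = 0.054). 5 more lists passed with the preset correlation at medians from 0.14 to 0.26, among them TGF-beta response (0.26; adjusted p = 0.019, but adjusted p = 0.195 with an estimated correlation) and p53 and senescence (0.22; adjusted p = 0.0452, but adjusted p = 0.553 with an estimated correlation).

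Cilengitide moved few genes past the test in knockout fibroblast-like cells (n = 3 and 4 libraries with at least 10 cells). Lcn2 (ENSMUSG00000026822, neutrophil gelatinase-associated lipocalin) rose by 4.81 ± 0.83 (log2 fold change ± SE; adjusted p = 0.0257), from 19.8 ± 13.7 to 592 ± 526 CPM (SD), and Dio2 (ENSMUSG00000007682, thyroid hormone deiodinase) by 3.55 ± 0.61 (adjusted p = 0.0257). Grm7 (ENSMUSG00000056755, metabotropic glutamate receptor) rose by 3.41 ± 0.53 (adjusted p = 0.0257). St6galnac5 (ENSMUSG00000039037, sialyltransferase) rose by 4.34 ± 0.77 (adjusted p = 0.0292) and Ifit1 by 4.33 ± 0.88 (adjusted p = 0.0439). Ly6a (ENSMUSG00000075602, stem cell antigen 1) fell by 3.84 ± 0.63 (adjusted p = 0.0257), Pdgfb (ENSMUSG00000000489, platelet-derived growth factor B) by 4.01 ± 0.74 (adjusted p = 0.0318), Agbl4 (ENSMUSG00000061298, tubulin deglutamylase) by 4.36 ± 0.82 (adjusted p = 0.0339) and Srd5a1 (ENSMUSG00000021594, steroid 5-alpha-reductase) by 4.47 ± 0.90 (adjusted p = 0.0439). Ccdc148 (ENSMUSG00000036641, coiled-coil protein) fell by 4.76 ± 0.91 (adjusted p = 0.0346). For each of these 10 genes all 3 cilengitide libraries lay on one side of all 4 knockout libraries, but each lost its call in 3 to 6 of 7 runs with 1 library left out (highest adjusted p 0.154 to 0.294). With doublets kept, Lcn2 had -0.04 (adjusted p = 0.995). In all, 20 genes rose and 39 fell among 6224 tested, and the test recovered 23% of 200 genes changed in simulated data. Several rested on few UMIs in one group: Ccdc148 on 2 against 48 (ratio of untreated to treated 37.4, 95% exact counting interval 9.79 to 317), Agbl4 on 3 against 50 (25.9, interval 8.38 to 130.04), St6galnac5 on 63 against 2 (ratio of treated to untreated 20.2, interval 5.37 to 171) and Ifit1 on 58 against 2 (18.6, interval 4.93 to 157). Another split of the same 7 libraries gave more genes than the real groups, 130 against 59.

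The deleted gene and the drug's target were not shown to move in these cells. Col5a1 had 1.02 ± 0.44 (adjusted p = 0.288), Itgav -0.07 ± 0.36 (adjusted p = 0.942) and Itgb5 0.10 ± 0.36 (adjusted p = 0.915), and the collagen and matrix list had a median of 0.42 over 35 members (adjusted p = 0.0762). Interferon response genes had a median of 0.86, with 1 of 17 members higher over all genes and 7 adjusted over the list alone (adjusted p = 1.07e-04, but adjusted p = 0.43 with an estimated correlation). Isg15 (ENSMUSG00000035692) had 1.96 ± 0.48 (adjusted p = 0.082). The mitochondrially encoded list had a median of 0.78 (0 members past the test over all genes, 5 adjusted over the list alone; adjusted p = 1.78e-04, but adjusted p = 0.635 with an estimated correlation). Tubule injury genes had a median of -1.19 over 26 members, with 2 lower and 1 higher over all genes and 6 and 1 adjusted over the list alone (adjusted p = 0.00149, but adjusted p = 0.635 with an estimated correlation). Sox9 fell by 2.88 ± 0.50.

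In proximal tubule-like cells of knockout mice, cilengitide raised the injury marker Havcr1 (ENSMUSG00000040405, KIM-1) (n = 4 and 4). Havcr1 rose by 1.51 ± 0.23 (log2 fold change ± SE; adjusted p = 0.00212), from 76.7 ± 11.3 to 218 ± 62.8 CPM (SD). Slc7a12 (ENSMUSG00000039710, amino acid transporter of females) rose by 2.31 ± 0.23 (adjusted p = 1.32e-04), from 11.5 ± 2.79 to 56.5 ± 16.9 CPM. Kcnk1 (ENSMUSG00000033998, potassium channel) rose by 1.31 ± 0.17 (adjusted p = 8.20e-04), Slc22a19 (ENSMUSG00000024757, organic anion transporter) by 1.32 ± 0.28 (adjusted p = 0.0154) and Hspb1 (ENSMUSG00000004951, small heat shock protein) by 1.37 ± 0.18 (adjusted p = 9.38e-04), the last open to free RNA. Fabp1 fell by 1.83 ± 0.40 (adjusted p = 0.0213), from 31.0 ± 25.6 to 8.67 ± 2.25 CPM, a call lost in 3 of 8 runs with 1 library left out (-1.08 without knockout 1), as that of Slc22a19 was in 2. Slc16a1 (ENSMUSG00000032902, lactate transporter) fell by 1.36 ± 0.11 (adjusted p = 3.86e-05) and S100g (ENSMUSG00000040808, vitamin D-dependent calbindin) by 1.63 ± 0.19 (adjusted p = 5.08e-04). Slc38a3 (ENSMUSG00000010064, glutamine transporter) fell by 1.75 ± 0.27 (adjusted p = 0.00212). The groups' libraries did not overlap in these 9 genes. In all, 207 genes rose and 242 fell among 13472 tested.

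The fatty acid oxidation list was lower with cilengitide, with a median of -0.32 over 30 members, of which 8 fell over all genes and 17 adjusted over the list alone (camera, adjusted p = 3.02e-13, but adjusted p = 0.36 with an estimated correlation). The heat shock list was higher, with a median of 0.31 over 13 members, of which 5 rose over all genes and 9 adjusted over the list alone (adjusted p = 3.02e-13, but adjusted p = 0.143 with an estimated correlation). The tubule injury list had a median of 0.20, with 3 higher over all genes and, adjusted over the list alone, 5 higher and 1 lower (adjusted p = 0.00835, but adjusted p = 0.6 with an estimated correlation). The oxidative stress and metallothionein list had a median of -0.20, with 1 lower over all genes and 5 adjusted over the list alone (adjusted p = 0.00132, but adjusted p = 0.595 with an estimated correlation). The cell cycle list had a median of 0.25, with 2 higher over all genes and 3 adjusted over the list alone (adjusted p = 0.0112, but adjusted p = 0.595 with an estimated correlation). The proximal tubule transport list had a median of 0.08, with 4 higher and 1 lower over all genes and 8 and 5 adjusted over the list alone (adjusted p = 0.0445, but adjusted p = 0.595 with an estimated correlation). Among circadian and glucocorticoid genes (median 0.18; adjusted p = 0.0329, but adjusted p = 0.6 with an estimated correlation) Dbp rose by 1.24 ± 0.17 and Arntl (ENSMUSG00000055116, core clock activator) fell by 1.30 ± 0.19. MHC class II genes had a median of -0.25 with 0 members past the test on either adjustment (adjusted p = 0.0445, but adjusted p = 0.65 with an estimated correlation).

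Changes of the knockout and of cilengitide ran in opposite directions across genes of proximal tubule-like cells. Of genes past the test in both contrasts, 114 rose in the knockout and fell with cilengitide (18.1 expected if the calls were independent) and 108 fell and then rose (13.8 expected). 2 rose in both (15.5 expected) and 7 fell in both (16.1 expected). The 2 contrasts share the 4 untreated knockout libraries, which by itself makes the correlation across genes negative: it was -0.38, against a mean of -0.45 in 20 simulations without any change. With the knockout libraries divided into separate pairs for the 2 contrasts, the correlation over 6 divisions averaged -0.23 (-0.29 to -0.19), and on average 60.7 genes were called in opposite and 1.83 in the same directions. The covariance of -0.0634 was also lower than the -0.0213 of the simulations. In injured tubule-like cells 7 genes rose and then fell and 10 fell and then rose (0.139 and 0.205 expected if independent). The correlation there was -0.37, as in the simulations (-0.37), and with separate pairs it was -0.17, with 1.33 opposite calls on average. The covariance was -0.0510, against -0.0256 simulated. Genes are not independent replicates, so no p-value is attached to these correlations.

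**Figure D3:**
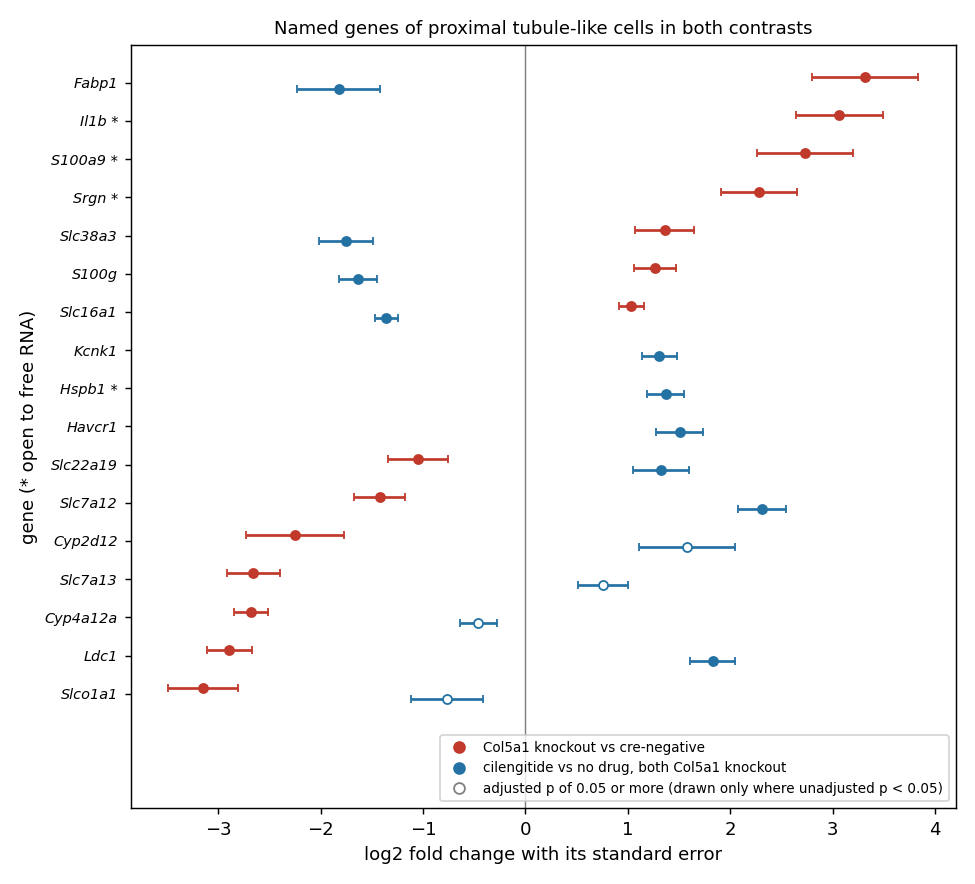
Log2 fold change with its standard error of genes named in proximal tubule-like cells, for knockout against cre-negative (n = 4 and 3 libraries) and for cilengitide against no drug in knockout mice (n = 4 and 4), with open symbols for an adjusted p of 0.05 or more. Fabp1 lies at 3.32 in the knockout and at -1.83 with cilengitide.

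In injured tubule-like cells of knockout mice, cilengitide raised Igfbp5 (ENSMUSG00000026185, insulin-like growth factor-binding protein) by 1.26 ± 0.11 (log2 fold change ± SE; adjusted p = 1.02e-04), from 36.5 ± 2.82 to 87.6 ± 13.6 CPM (SD, n = 4 and 4), and Hsd3b2 (ENSMUSG00000063730, steroid dehydrogenase) by 1.70 ± 0.22 (adjusted p = 0.00268). The clock gene Arntl fell by 1.43 ± 0.16 (adjusted p = 0.00171). Rgs5 (ENSMUSG00000026678, regulator of G protein signalling) had -1.36 ± 0.28 (adjusted p = 0.0474), a call lost in 8 of 8 runs with 1 library left out. In all, 34 genes rose and 37 fell. The immediate early and dissociation list had a median of -0.27, with 1 of 20 members lower over all genes and 7 adjusted over the list alone (camera, adjusted p = 1.05e-08, but adjusted p = 0.793 with an estimated correlation). The interferon response list had a median of 0.49, with 1 of 22 higher over all genes and 6 adjusted over the list alone (adjusted p = 1.01e-05, but adjusted p = 0.793 with an estimated correlation). Tubule injury genes had a median of -0.23, with 1 of 30 lower over all genes and 4 adjusted over the list alone (adjusted p = 5.49e-05, but adjusted p = 0.793 with an estimated correlation). Endothelial activation and angiogenesis genes had a median of -0.39 (1 lower over all genes, 5 adjusted over the list alone; adjusted p = 0.0015, but adjusted p = 0.793 with an estimated correlation). 6 more lists passed with the preset correlation at medians from -0.14 (TGF-beta response; adjusted p = 0.0164, but adjusted p = 0.804 with an estimated correlation) to 0.34 (mitochondrially encoded; adjusted p = 3.38e-04, but adjusted p = 0.793 with an estimated correlation). Of the 10 lists 0 held with an estimated correlation.

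In endothelial-like cells of knockout mice, 5 genes rose and 0 fell with cilengitide by the edgeR quasi-likelihood test (n = 4 and 4), 629 of 9593 at an unadjusted p under 0.05, and DESeq2 called 9 higher and 1 lower. Lcn2, an injury-induced tubule and neutrophil transcript, rose by 3.01 ± 0.46 (log2 fold change ± SE; adjusted p = 0.0154), from 11.7 ± 4.45 to 100.4 ± 74.3 CPM (SD), and Kng2 (ENSMUSG00000060459, kininogen) by 2.03 ± 0.32 (adjusted p = 0.0201), both open to free RNA. With doublets kept, Lcn2 had 1.24 (adjusted p = 0.933), and with 1 library left out the calls of Lcn2 and Kng2 were lost in 3 and 6 of 8 runs. The immediate early and dissociation list had a median of -0.23, with 0 of 20 members past the test over all genes and 1 adjusted over the list alone (camera, adjusted p = 2.06e-09, but adjusted p = 0.392 with an estimated correlation). The mitochondrially encoded list had a median of 0.29 (adjusted p = 4.31e-06, but adjusted p = 0.411 with an estimated correlation). MHC class II had 0.28 (adjusted p = 0.00544, but adjusted p = 0.411 with an estimated correlation), and 0 members of either list passed on either adjustment. Interferon response genes had a median of 0.17, with 0 past the test over all genes and 4 adjusted over the list alone (adjusted p = 0.00137, but adjusted p = 0.466 with an estimated correlation). Tubule injury genes had a median of 0.20, with Lcn2 past the test over all genes and, adjusted over the list alone, 3 higher and 1 lower (adjusted p = 7.47e-04, but adjusted p = 0.298 with an estimated correlation).

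Macrophage-like cells of knockout mice had higher cell cycle genes and lower oxidative stress genes with cilengitide (n = 4 and 4). Gpnmb (ENSMUSG00000029816, osteoactivin) fell by 2.04 ± 0.43 (log2 fold change ± SE; adjusted p = 0.0167), from 301 ± 103 to 72.7 ± 11.4 CPM (SD), a call lost in 3 of 8 runs with 1 library left out. Lyz1 (ENSMUSG00000069515, lysozyme) fell by 2.45 ± 0.35 (adjusted p = 0.00260). Saa3 (ENSMUSG00000040026, serum amyloid A3) rose by 2.02 ± 0.34 (adjusted p = 0.00538), from 21.001 ± 4.99 to 87.2 ± 35.9 CPM. Pclaf (ENSMUSG00000040204, PCNA-associated factor) rose by 1.82 ± 0.25 (adjusted p = 0.00249). In all, 248 genes rose and 270 fell. The cell cycle list had a median of 1.23, with 20 of 25 members higher over all genes and 23 adjusted over the list alone (camera, adjusted p = 3.11e-34, and adjusted p = 0.0442 with an estimated correlation). Ccnb2 rose by 1.25 ± 0.15 and Cenpf (ENSMUSG00000026605, kinetochore protein) by 1.71 ± 0.24. A cycling cluster made up 2.42% of the class in the knockout and 7.28% with cilengitide. The oxidative stress and metallothionein list had a median of -0.37, with 4 of 20 lower over all genes and 11 adjusted over the list alone (adjusted p = 2.86e-07, and adjusted p = 0.0245 with an estimated correlation). Srxn1 fell by 0.71 ± 0.11 and Slc7a11 by 1.20 ± 0.22. The scar-associated macrophage list had a median of -0.61, with 7 of 22 lower over all genes and, adjusted over the list alone, 11 lower and 1 higher (adjusted p = 4.06e-08, but adjusted p = 0.2 with an estimated correlation). Arg1 fell by 1.59 ± 0.29 and Cd63 (ENSMUSG00000025351, lysosomal tetraspanin) by 0.83 ± 0.18. Heat shock genes had a median of 0.34 (3 higher over all genes, 7 adjusted over the list alone; adjusted p = 1.69e-04, but adjusted p = 0.304 with an estimated correlation). TGF-beta response genes had a median of -0.22 (1 lower over all genes, 2 adjusted over the list alone; adjusted p = 0.0145, but adjusted p = 0.2 with an estimated correlation). Interferon response genes had a median of 0.15 (1 higher over all genes, 2 adjusted over the list alone; adjusted p = 0.0145, but adjusted p = 0.756 with an estimated correlation).

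**Figure D4:**
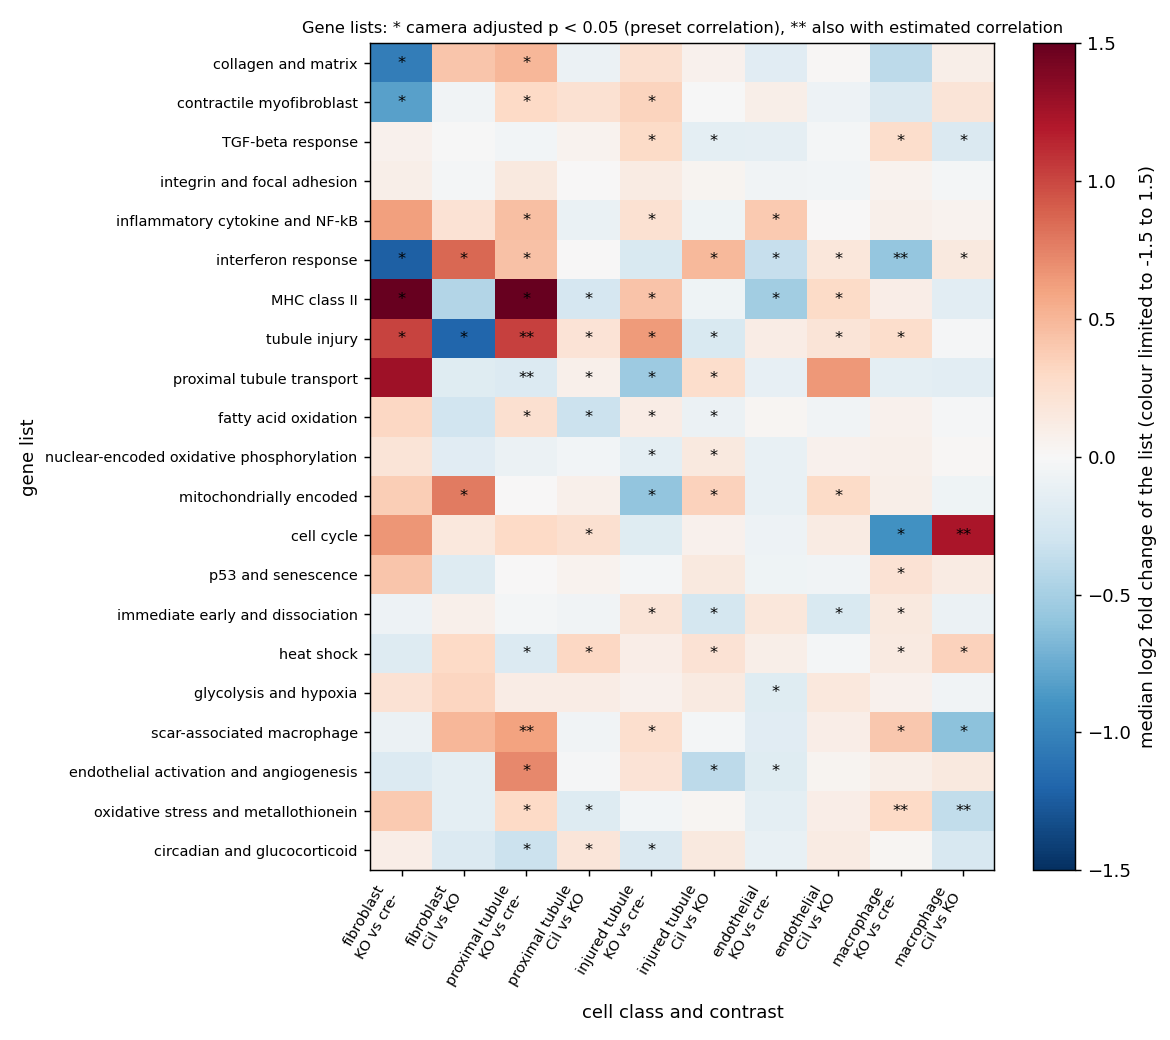
Median log2 fold change of the 21 gene lists (vertical axis) in the 5 main cell classes under both contrasts (horizontal axis), with 1 star for a camera adjusted p under 0.05 with the preset correlation and 2 stars where it also held with an estimated correlation. Cell cycle genes of macrophage-like cells have medians of -0.91 in the knockout and 1.23 with cilengitide.

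Set against cre-negative libraries, proximal tubule-like cells of knockout mice given cilengitide still differed in 1441 genes (742 higher, 699 lower; n = 4 and 3). Slco1a1 was lower by a log2 fold change of -3.92 ± 0.36 (SE; adjusted p = 2.11e-05), Cyp4a12a by -3.14 ± 0.17 (adjusted p = 1.09e-07) and Acsm3 (ENSMUSG00000030935, acyl-CoA synthetase) by -3.08 ± 0.42 (adjusted p = 3.07e-04). Ccdc152 (ENSMUSG00000091119) had -2.16 ± 0.28 (adjusted p = 2.09e-04) and Slc7a13 -1.90 ± 0.26 (adjusted p = 2.95e-04). The largest rises were in S100a9 (3.34 ± 0.47), S100a8 (ENSMUSG00000056054, calprotectin subunit) (3.06 ± 0.47), Srgn (2.19 ± 0.37), Cd14 (ENSMUSG00000051439, lipopolysaccharide co-receptor) (1.87 ± 0.18) and Anxa2 (ENSMUSG00000032231, annexin A2) (1.76 ± 0.17), all open to free RNA. With such genes left out, 505 were higher and 692 lower. The tubule injury list had a median of 1.19, with 21 of 28 members higher over all genes and 23 adjusted over the list alone (camera, adjusted p = 3.15e-33, and adjusted p = 0.0342 with an estimated correlation). Spp1 was higher by 1.27 ± 0.15, and Anxa2 and Lgals3 (1.56 ± 0.16) were higher and open to free RNA. The scar-associated macrophage list also held with an estimated correlation (median 0.51, adjusted p = 1.46e-07, and adjusted p = 0.0346 with an estimated correlation), with Ctsb higher by 0.63 ± 0.10. Its source was not tested here either. The proximal tubule transport list had a median of -0.11 (5 lower and 1 higher over all genes, 7 and 1 adjusted over the list alone; adjusted p = 1.68e-04, but adjusted p = 0.0519 with an estimated correlation), with Slc22a30 lower (-1.44 ± 0.17). MHC class II genes had a median of 1.39, with 8 of 9 higher on either adjustment and the 4 of smallest p, H2-Eb1, H2-Ab1, Ctss (ENSMUSG00000038642, cathepsin S) and Cd74, open to free RNA (adjusted p = 1.5e-12, but adjusted p = 0.0796 with an estimated correlation). 9 more lists passed with the preset correlation alone.

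List changes were also compared between classes. In 16 tests of lists that passed with opposite signs in 2 classes, 9 reached the smallest exact permutation p of 0.0286 and 0 passed after adjustment (smallest adjusted p = 0.0508). The interferon response list differed between proximal tubule-like and macrophage-like cells of the knockout contrast by 0.98 on the log2 scale, and the collagen and matrix list between proximal tubule-like and fibroblast-like cells by 2.20, both with an adjusted p of 0.0508 by the exact permutation test.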

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

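All 6 tests of technical explanations given in this part were chosen after the results were seen; the comparison with other splits was written before the splits were run.

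In 168 groups of 4 libraries, 12 had 1 library far from the other 3 by Dixon's test, where chance gives 8.4 (about 1 in 20). In the knockout group, replicate 1 had a T or NK cell-like share of 31.7% (others 28.6 to 28.9%), and in its proximal tubule-like cells Cyp2d12 stood at 8.44 CPM (others 3.44 to 4.18) and Slc38a3 at 24.5 (53.8 to 59.4). Replicate 2 had 1045 normalized CPM of Itgav in fibroblast-like cells (376 to 413) and 10.3 CPM of Hsd3b2 in injured tubule-like cells (6.50 to 7.11). Replicate 3 had 5.18 CPM of Rbp4 (others 0) and 41.5 CPM of Smoc2 (5.84 to 7.81) in fibroblast-like cells, and replicate 4 had 42.7 CPM of Nipal2 in endothelial-like cells (27.2 to 29.5). With cilengitide, replicate 2 had a dendritic cell-like share of 3.19% (1.77 to 1.95%) and 9.002 CPM of Arntl in injured tubule-like cells (7.24 to 7.37), and replicate 3 had 46.5 CPM of Pkp2 in fibroblast-like cells (11.1 to 12.2) and 9.18 CPM of Cyp4a12a in proximal tubule-like cells (6.48 to 6.88).

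The share of leukocytes was 67.3% in the knockout and 27.3% in the cre-negative group. A lower yield of tubule cells would leave the mix of leukocytes alone. T or NK cell-like cells were 43.9% of leukocytes in the knockout and 63.0% in the cre-negative group (exact permutation p = 0.0286, adjusted p = 0.0571). This did not pass adjustment, and the mix can shift at any yield, so yield stays open. Few barcodes in cre-negative replicates 1 and 2 could also matter. Replicate 3, with 8683 barcodes, still lay 26.9 percentage points below the lowest knockout library, but 1 library excludes nothing. The deletion, yield and cell calling cannot be told apart, since every cre-negative library differs from the knockout in genotype and the libraries with few barcodes are all cre-negative.

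In proximal tubule-like cells of the knockout, neutrophil markers (6 of 6 higher, median 2.54) and macrophage markers (7 of 11 higher, median 1.76) rose. Free RNA may be their source, since it gives all leukocyte markers a like ratio to the whole library, and the medians of 5 leukocyte marker lists in the knockout (0.0162 to 0.0242) differed by a factor of 1.49. MHC class II genes had a ratio of 0.0998, and 6 of the 9 still separated every knockout from every cre-negative library once the highest leukocyte ratio of each library was taken off (8 before; median log2 ratio of those 6 genes 1.58 after and 1.71 before), which argues against free RNA as the whole source. Doublets with dendritic cells, macrophages or B cells would bring their markers at a like ratio. The class II ratio was at least 2.37 times theirs in each knockout library. It was 0.143 in cre-negative libraries, so it cannot tell if doublets gave the rise. Class II expression by injured tubule cells is a hypothesis found and tested on the same data.

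The clock genes Dbp and Arntl moved in opposite directions with cilengitide in 7 of 9 classes (8 of 9 between knockout and cre-negative), as in proximal tubule-like cells (1.24 ± 0.17 and -1.30 ± 0.19). A difference in the time of day of collection could give this, and an effect of drug or genotype could too. The labels give no time of collection, so the explanations cannot be told apart.

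Other splits of the same libraries into groups of the same sizes, 35 for each comparison, bear on whether chance alone could give as many genes. In 22 of 23 comparisons only the real split gave so many. At 1 of 35, the smallest share possible and not adjusted for 23 comparisons, this argues against chance without excluding it. The counts of 5, 3 and 2 given here fell to 0 or 1 without 1 library. For knockout against cre-negative the real and the highest other counts were 1903 and 313 (proximal tubule-like), 125 and 0 (injured tubule-like), 104 and 38 (endothelial-like), 84 and 0 (macrophage-like), 30 and 6 (fibroblast-like), 1754 and 0 (T or NK cell-like), 230 and 3 (neutrophil-like), 614 and 58 (thick ascending limb-like), 446 and 123 (distal tubule-like) and 46 and 0 (pericyte or smooth muscle-like). For cilengitide in knockout mice they were 449 and 2 (proximal tubule-like), 71 and 1 (injured tubule-like), 5 and 1 (endothelial-like), 518 and 1 (macrophage-like), 232 and 2 (T or NK cell-like), 958 and 2 (neutrophil-like), 11 and 3 (dendritic cell-like), 1141 and 1 (B or plasma cell-like), 43 and 2 (thick ascending limb-like), 3 and 2 (distal tubule-like) and 2 and 0 (pericyte or smooth muscle-like). For cilengitide against cre-negative they were 1441 and 126 in proximal tubule-like cells. For cilengitide in fibroblast-like cells the splits do not argue against chance, since 2 of 35 gave at least the real 59 genes. The split that set knockout replicates 2, 3 and 4 apart gave 130. That split is the real one with knockout 1 moved to the drug's side, and without knockout 1 the real groups gave 188, which points to a structure of the samples in which knockout 1 stands apart.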

How the results depend on the processing

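The 5-cell minimum, leaving out genes open to free RNA, shares outside leukocyte classes, and leaving out clusters or cre-negative replicates 1 and 2 were chosen after the results were seen; the others were set before the data were examined. Of the values of 127 named gene results, 78 of 78 under RLE size factors, 115 of 127 under DESeq2, 100 of 127 with a replicate block, 73 of 77 at Leiden resolution 2, 65 of 78 under the 20% mitochondrial limit, 60 of 78 with doublets kept and 735 of 921 with 1 library left out (5 reversed) had the same direction and side of the threshold. The cause was not tested for any change given here except where fewer samples, genes or UMIs explain it. A sex covariate was not run, since all libraries were male, and the 10-cell minimum gave no test of fibroblast-like cells in the knockout contrast.

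Counts of genes are given against 1903 (knockout) and 449 (cilengitide) in proximal tubule-like, 125 and 71 in injured tubule-like, 104 and 5 in endothelial-like, 84 and 518 in macrophage-like and 30 and 59 in fibroblast-like cells, and 1441 for cilengitide against cre-negative in proximal tubule-like cells. DESeq2 gave 122 and 141 (fibroblast-like), 386 and 235 (injured), 184 and 10 (endothelial) and 418 (macrophage, knockout). RLE gave 3 (endothelial, cilengitide). No low-count filter gave 445 and 624 (fibroblast-like), 871 (proximal tubule, cilengitide), 463 and 363 (injured), 410 and 114 (endothelial) and 424 and 826 (macrophage). With only the 2 compared groups in the fit, 827 were called in proximal tubule-like cells with cilengitide, 24 and 406 in injured, 63 and 21 in endothelial and 0 and 1323 in macrophage-like cells. Doublets kept gave 294 (fibroblast-like, knockout), 213 and 146 (injured) and 37 and 0 (endothelial). The 20% mitochondrial limit gave 136 (cilengitide) and 836 (cilengitide against cre-negative) in proximal tubule-like, 1 and 18 in injured and 2 in endothelial-like cells (cilengitide). Leiden resolution 2 gave 595 (injured, knockout) and 3184 (proximal tubule, cilengitide against cre-negative). Thinning to equal UMIs, which removes depth, gave 17 (fibroblast-like, cilengitide), 71 and 12 (injured) and 1 and 2 (macrophage). Without genes open to free RNA 3 remained called in endothelial-like cells (cilengitide), without the cycling cluster 40 and 107 in macrophage-like cells, and without a cluster filled by 1 library 155 in injured tubule-like cells (cilengitide).

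Replicate numbers did not pair the libraries (3 of 10 pairs correlated above 0.1 over all cells, r -0.27 to 0.44), so a block on them says nothing of an effect. With the block the counts were 1268, 299 and 935 in proximal tubule-like, 10 and 22 in injured, 8 in endothelial (cilengitide), 9 and 256 in macrophage and 5 and 2 in fibroblast-like cells. With the block Itgb5 with cilengitide was -0.09 (-0.0906), and the paired share differences were -0.276 (fibroblast-like), -13.5 (proximal tubule-like), -2.43 (endothelial-like) and 7.11 points (macrophage-like), where 3 pairs cannot give a sign-permutation p below 0.25.

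With 1 library left out the counts were, in proximal tubule-like knockout 1230 (without cre-negative 3) to 1959, cilengitide 231 (without cilengitide 4) to 357, and cilengitide against cre-negative 873 (without cilengitide 4) to 1427. Other ranges were injured 14 (without knockout 4) to 444 (without cre-negative 2), and 12 (without cilengitide 3) to 24; endothelial 11 (without knockout 4) to 162 (without cre-negative 3), and 0 (without knockout 3) to 12 (without knockout 1). In the remaining classes they were macrophage 9 (without knockout 3) to 198 (without cre-negative 2), and 230 (without knockout 1) to 321; fibroblast-like 3 (without knockout 2) to 68 (without knockout 1), and 0 (without knockout 3) to 188 (without knockout 1). In further classes, wide ranges were, for the knockout, neutrophil 50 (without cre-negative 3) to 257, thick ascending limb 277 (without cre-negative 1) to 900, distal 80 (without cre-negative 1) to 671 (without cre-negative 2), pericyte 25 (without knockout 1) to 125 (without cre-negative 3), B or plasma 4 (without knockout 3) to 82 (without cre-negative 3) and dendritic 0 to 130 (without cre-negative 3), and with cilengitide T or NK 106 (without knockout 4) to 220, neutrophil 546 (without cilengitide 4) to 1242, thick ascending limb 16 (without knockout 1) to 45, dendritic 3 (without cilengitide 3) to 17 (without cilengitide 2), distal 1 (without cilengitide 2) to 15 (without knockout 4) and pericyte 0 (without knockout 1) to 3. There DESeq2 gave 54 (B or plasma) and 78 (pericyte) for the knockout, and 83 (distal), 95 (thick ascending limb) and 4 (pericyte) with cilengitide, and the block 373 (thick ascending limb), 8 (B or plasma) and 27 (pericyte), and 20 (distal) and 0 (pericyte). Share differences lay between -0.392 and -0.195 points (fibroblast-like), -15.6 and -11.5 (proximal tubule-like), -3.24 and -1.92 (endothelial-like), -17.8 and -9.89 (thick ascending limb-like), -5.20 and -1.63 (distal tubule-like, -1.63 without cre-negative 1) and 6.65 and 7.82 (macrophage-like), with adjusted p from 0.0778 to 0.14, since 6 libraries cannot give a smaller exact p.

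The log2 fold change of Col5a1 in knockout fibroblast-like cells passed with DESeq2 (-1.97, adjusted p = 0.0317) and with doublets kept (-1.97, adjusted p = 0.00752), and ranged from -2.30 (without cre-negative 3) to -1.25 (without cre-negative 2). With cilengitide, Itgav ranged from -0.24 to 0.42 (positive without knockout 2, 0.42, or cilengitide 2, 0.03) and Itgb5 from -0.14 to 0.33 (negative without knockout 2, -0.04, knockout 3, -0.11, or cilengitide 2, -0.14). Lcn2 with cilengitide in fibroblast-like cells was -0.04 (-0.0393) with doublets kept. Outside leukocyte classes the proximal tubule-like share differed by 3.29 points, the fibroblast-like by -0.0402 and the endothelial-like by -0.528. Of 89 list results, 9 passed with an estimated correlation, 31 with fry and 56 with every library left out in turn. The reversal correlation with the knockout libraries split into separate pairs was -0.23.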

Other observations

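The tests in 7 further classes given here were chosen after the results were seen. In leukocytes of the knockout against the cre-negative group, 1026 genes rose and 728 fell in T or NK cell-like cells, 120 and 110 in neutrophil-like cells and 4 and 12 in B or plasma cell-like cells. Mcc (ENSMUSG00000071856) (3.25 ± 0.38, log2 fold change ± SE) and Lyz2 (2.89 ± 0.46, open to free RNA) rose in T or NK cell-like cells. Csf2 (ENSMUSG00000018916, GM-CSF) fell by 2.26 ± 0.41 there. P2rx7 (ENSMUSG00000029468, ATP receptor) rose by 2.81 ± 0.33 and Gbp2 (ENSMUSG00000028270, interferon-induced GTPase) fell by 1.72 ± 0.23 (-1.14 without cre-negative 2) in neutrophil-like cells. Neat1 (ENSMUSG00000092274) rose by 1.00 ± 0.19 and P4ha1 (ENSMUSG00000019916, prolyl hydroxylase) fell by 1.64 ± 0.24 in B or plasma cell-like cells, calls lost in 4 and 1 of 6 runs with 1 library left out. In dendritic cell-like cells (n = 4 and 2) edgeR called 0 of 9651 genes, 1038 at an unadjusted p under 0.05, and DESeq2 51. Cd14 had 1.59 ± 0.27 (adjusted p = 0.11), Glis3 (ENSMUSG00000052942) 2.24 ± 0.38 (adjusted p = 0.11) and Adam23 (ENSMUSG00000025964) -1.53 ± 0.28 (adjusted p = 0.149). The interferon response list was lower in T or NK (median -0.71; adjusted p = 8.21e-21, but adjusted p = 0.135 with an estimated correlation). It was also lower in neutrophil (-0.72; adjusted p = 1.79e-23, but adjusted p = 0.0812 with an estimated correlation), dendritic (-0.55; adjusted p = 1.8e-04, but adjusted p = 0.6 with an estimated correlation) and B or plasma cell-like cells (-0.45; adjusted p = 3.18e-06, but adjusted p = 0.154 with an estimated correlation). In tubule and mural cells 433 genes rose and 181 fell in thick ascending limb-like (250 and 180 without genes open to free RNA), 318 and 128 in distal tubule-like and 33 and 13 in pericyte or smooth muscle-like cells. Cenpa (ENSMUSG00000029177) fell by 2.17 ± 0.27 in distal tubule-like cells. Plat (ENSMUSG00000031538, tissue plasminogen activator) rose by 1.89 ± 0.23 and Stmn1 (ENSMUSG00000028832) fell by 3.64 ± 0.63 in pericyte or smooth muscle-like cells (without cre-negative 2, -2.19 and adjusted p = 0.0985). Nme7 (ENSMUSG00000026575) fell by 0.79 ± 0.13 in thick ascending limb-like cells, where Il1b rose by 3.91 ± 0.44 and was open to free RNA. The distal tubule-like immediate early and dissociation list was higher (median 0.67; adjusted p = 6.5e-34, and adjusted p = 0.00511 with an estimated correlation). The cell cycle list was lower there (-1.21; adjusted p = 1.13e-26, and adjusted p = 0.0325 with an estimated correlation). The integrin and focal adhesion list passed there alone (0.13; adjusted p = 0.00807, but adjusted p = 0.13 with an estimated correlation).

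With cilengitide in knockout mice, 94 genes rose and 138 fell in T or NK cell-like, 471 and 487 in neutrophil-like, 357 and 784 in B or plasma cell-like, 0 and 11 in dendritic cell-like (edgeR; 988 at an unadjusted p under 0.05, 21 and 52 by DESeq2), 26 and 17 in thick ascending limb-like, 1 and 2 in distal tubule-like and 1 and 1 in pericyte or smooth muscle-like cells. Ccl1 (ENSMUSG00000020702) rose by 2.09 ± 0.39 in T or NK cell-like cells. Ccl2 (ENSMUSG00000035385) rose by 2.66 ± 0.30 and Id3 (ENSMUSG00000007872) by 1.68 ± 0.16 in neutrophil-like cells. Sox5 (ENSMUSG00000041540) rose by 2.00 ± 0.30 and Ica1 (ENSMUSG00000062995) fell by 2.44 ± 0.27 in B or plasma cell-like cells. A plasma cell cluster, 19.6% of that class without and 5.26% with the drug, was not separated. Cd209d (ENSMUSG00000031495) fell by 1.94 ± 0.25 in dendritic cell-like cells. Nupr1 (ENSMUSG00000030717) rose by 1.16 ± 0.19 and Rbm3 (ENSMUSG00000031167) fell by 0.82 ± 0.14 in thick ascending limb-like cells. Akr1b8 (ENSMUSG00000029762) had 1.16 ± 0.18 in distal tubule-like cells, a call lost in 5 of 8 runs with 1 library left out, as Rbm3's was in 1. In pericyte or smooth muscle-like cells Dbp had 1.35 ± 0.24 and Cirbp (ENSMUSG00000045193) -1.11 ± 0.19 (both adjusted p = 0.0409, lost in 6 and 7 of 8 such runs), and Col12a1 (ENSMUSG00000032332) had 1.08 ± 0.20 (adjusted p = 0.051). The heat shock list was higher in T or NK cell-like cells (median 0.64; adjusted p = 1.16e-35, and adjusted p = 0.0283 with an estimated correlation). With the drug the interferon response list was higher in T or NK (0.41; adjusted p = 9.49e-23, and adjusted p = 0.045 with an estimated correlation) and neutrophil-like cells (0.48; adjusted p = 5.79e-14, but adjusted p = 0.0735 with an estimated correlation). A change in one class and not in another was not shown to differ between them.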
